A study of Mus musculus with 12 samples.

How the data were processed

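Libraries were made from poly(A)-selected striatal RNA of 12 mice with a directional kit, per the labels' protocols. The deposited files hold whole-number counts per Ensembl gene for each library, and the alignment, the annotation, the genome build and the counting rule the authors used are not given in the sources used here. All 12 files list the same genes, of which 55141 (99.4%) were given a symbol from GENCODE M21 (GRCm38), and genes without one took at most 0.0611% of a library's counts. Groups and replicate numbers were read from the sample titles. The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to have been made after.

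Genes were kept by filterByExpr of edgeR (minimum count 10, minimum total 15) over the 4 groups, which left 21309 genes. Library sizes were scaled by TMM. One mean per group was fitted over all 12 libraries with edgeR's robust quasi-likelihood model, with 8 residual degrees of freedom and a common dispersion of 0.0326, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The 7 comparisons were HD against WT, cGAS-KO;HD against HD, cGAS-KO against WT, cGAS-KO;HD against cGAS-KO, their interaction, and the knock-in and cGAS effects each averaged over the other genotype. Errors of log2 changes are standard errors from the fit and those of CPM are standard deviations of 3 libraries. The labels give no sex, batch or litter, so no covariate was used.

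For genes with 0 counts over the 3 libraries of a group the text gives a bound at a floor of 3 counts over the group, and for 1 to 3 counts it gives the ratio with a 95% interval that covers counting error only.

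The 36 gene lists were written from general knowledge before the files were opened, and were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each with Benjamini-Hochberg adjustment over the lists of a comparison. They cover medium spiny neurons, synapses, interneurons, immediate early genes, silenced developmental transcription factors, interferon response, cGAS-STING components, inflammatory cytokines, antigen presentation, complement, microglia, disease-associated microglia, astrocytes, reactive astrocytes, oligodendrocytes and their precursors, endothelial and mural cells, fibroblasts, choroid plexus, cortical and thalamic neurons, erythrocytes, 6 lists of lipid metabolism, mitochondrially encoded and nuclear oxidative phosphorylation genes, autophagy, p53 and senescence, unfolded proteins, the circadian clock, sex-linked genes and C57BL/6 substrain genes. Members were counted by calls over all genes and by calls adjusted over the list alone. The named genes were chosen by rule: Htt and Cgas everywhere, for each pair of groups the 5 called genes with the largest log2 change each way among those with a mean of at least 1 CPM over 12 libraries and no overlap between the library values of both groups (an order that chance alone gives 10% of genes), for the interaction the 5 each way with the smallest p, up to 4 called members of each list by p or, where none was called, the member with the smallest p, and the 5 called genes with the smallest p each way for the averaged effects. Other genes (Ddx3y, Xist, Mid1 and those of the closing section outside these lists) were named after their values were seen.

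The knock-in effects with and without cGAS were compared by correlation, slope and overlap, and the cGAS effect in knock-in mice by the share of genes that changed opposite to the knock-in effect. Both were set against 20 simulated data sets without any effect and 20 with the knock-in effect alone, since the cGAS effect in knock-in mice and the knock-in effect share the HD libraries.

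The scripts were first run on simulated counts with 50 genes changed at each of 4 fold sizes. In HD against WT the fit recovered 15 genes at 1.5-fold, 37 at 2-fold, 36 at 4-fold and 48 at 8-fold, with 2 false calls among 146, the remaining calls being outside those counts, where a planted list of changed genes lies. Alternatives were DESeq2 size factors, no low-count filter, a stricter filter of 1 CPM in 3 libraries, DESeq2's Wald test, limma-voom, a fit on the compared groups alone, the replicate number as a block, and other thresholds, and each library was left out in turn. Counts of genes and lists were then taken for the comparisons whose groups held that library. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.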

Results

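Striatal RNA was measured in 12 libraries from 12 mice, 3 in each of 4 groups. The WT group were C57BL/6J controls. The HD group carried the zQ175 neo-deleted knock-in allele on one chromosome, an expanded CAG repeat placed in the mouse Htt gene that models Huntington's disease. The cGAS-KO group lacked cGAS, the enzyme that senses cytosolic DNA and signals through STING to type I interferon genes. The cGAS-KO;HD group, called the double mutants below, combined both alleles. The series asks whether loss of cGAS changes the course of disease in the knock-in mice. The files give whole-number read counts per Ensembl gene, with totals between 59195327 and 72765623 counts per library and 26827 to 28348 genes detected. Sex, age, litter and time of day at collection are not given in the sources used here.

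The libraries differed in ways that the group labels do not name. Xist, the RNA of the inactive X chromosome, was high in 6 libraries with near-absent counts of the Y-linked gene Ddx3y (WT replicate 1, HD replicates 1 and 2, cGAS-KO replicate 3 and double-mutant replicates 2 and 3) and low in the other 6. Each group thus held both kinds, but WT and cGAS-KO each had 1 high-Xist library while HD and the double mutants each had 2. Library cGAS-KO replicate 3 stood apart from the rest. Mitochondrially encoded genes took 11.5% of its counts, against 5.30% to 9.03% in the other 11 libraries, and its chi-square distance per gene to the other 2 cGAS-KO libraries was 142 and 176, against 8.61 to 73.1 for the pairs within the other 3 groups and 16.7 between the remaining cGAS-KO pair. The biological coefficient of variation over all libraries was 18.1%.

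The targeted genes came first. Htt fell in the knock-in groups, from 174 ± 5.27 CPM in WT to 139 ± 7.48 CPM in HD, and from 170 ± 13.2 CPM in cGAS-KO to 135 ± 8.19 CPM in the double mutants (mean ± SD, n = 3 each). The log2 changes were -0.32 ± 0.08 (SE, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, called the edgeR adjusted p from here on, 0.0389) and -0.33 ± 0.08 (edgeR adjusted p = 0.03). Htt did not pass the test for cGAS loss, at -0.03 ± 0.08 against WT and -0.04 ± 0.08 against HD. Cgas was a rare transcript in every group. It measured 1.41 ± 0.129 CPM in WT, 1.15 ± 0.0963 in HD, 0.777 ± 0.177 in cGAS-KO and 1.03 ± 0.203 in the double mutants, that is 277, 249, 142 and 220 counts over the 3 libraries of each group. Its log2 change in cGAS-KO against WT was -0.86 ± 0.24 (edgeR adjusted p = 0.919), and in the double mutants against HD -0.16 ± 0.23 (edgeR adjusted p = 0.856). Which part of Cgas the knockout allele removes is not given in the sources used here, so counts over the whole gene can keep reads from the part that remains, and they give only a weak check of the cGAS labels.

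**Figure D1:**
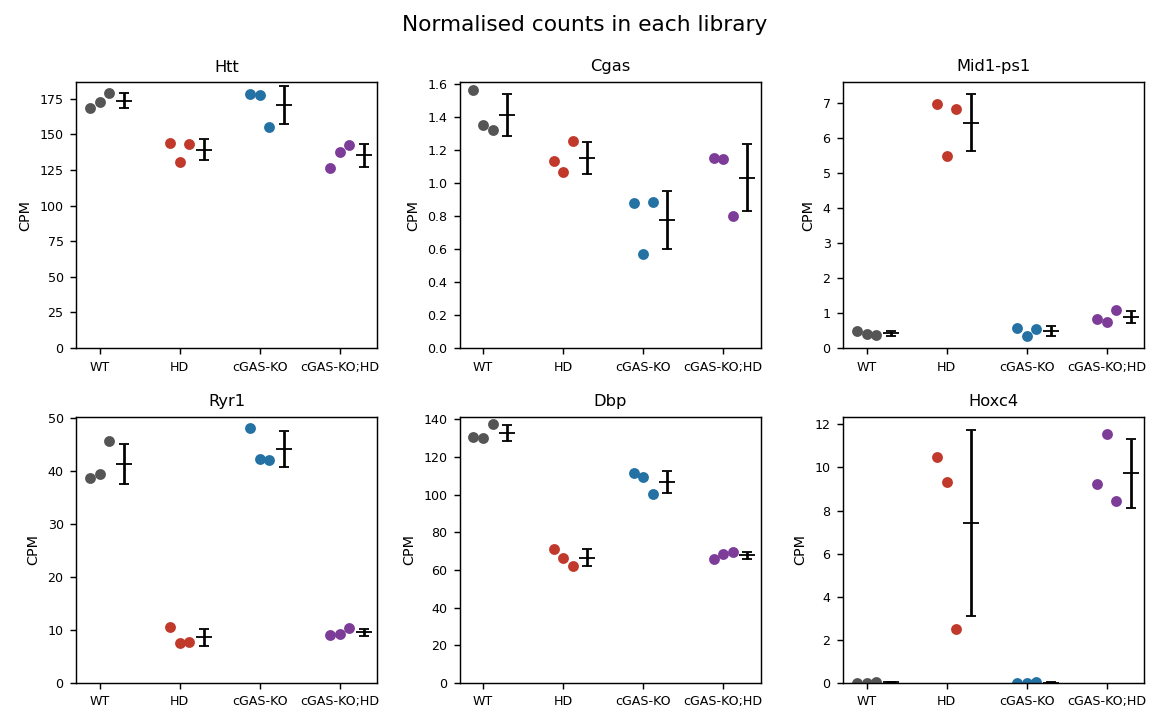
Normalised counts (CPM, linear axes from 0) of Htt, Cgas, Mid1-ps1, Ryr1, Dbp and Hoxc4 in each of the 12 libraries, by group, with dots for libraries and a bar with whiskers for the mean ± SD of 3 libraries. Ryr1 falls from 41.3 CPM in WT to 8.61 CPM in HD and Htt from 174 to 139 CPM, while Mid1-ps1 is high in HD alone at 6.43 CPM.

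HD against WT asks what the knock-in allele does to the striatum when cGAS is present. Genes of medium spiny neurons, the projection neurons that make up most of the striatum, fell together. Of 45 measured members of that list, 34 fell, none rose and 11 were not called, with log2 changes from -2.26 to -0.06 and a median of -1.06. Adjusted over the list alone, 44 fell. Ryr1, a calcium release channel, fell by 2.26 ± 0.13 on the log2 scale (edgeR adjusted p = 2.33e-06), from 41.3 ± 3.81 to 8.61 ± 1.59 CPM. Scn4b, a sodium channel subunit, fell by 2.17 ± 0.20 (edgeR adjusted p = 0.000164), from 573 ± 103 to 128 ± 11.4 CPM. Adora2a, the adenosine receptor of the indirect pathway, changed by -1.94 ± 0.20, and Rasgrp2, an exchange factor for Rap, by -1.07 ± 0.11 (edgeR adjusted p = 0.000442 and 0.00024). The list test passed with a preset correlation (camera adjusted p = 4.57e-75), with an estimated correlation (adjusted p = 0.0463) and with fry (adjusted p = 0.00346).

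Developmental transcription factors that are silent in the adult striatum rose in HD. In that list of 40 genes, 21 passed the low-count filter and were tested, and 6 of them rose (10 adjusted over the list alone). The other 19 had too few counts in every group to test, and a gene near 0 counts in WT can rise but hardly fall, so the absence of falls carries little weight. The camera adjusted p was 4.28e-12 (2.78e-10 without the low-count filter), and the adjusted p was 0.0405 with an estimated correlation. Hoxc genes, which pattern the posterior body axis in the embryo, had the largest fold changes among called genes of at least 1 CPM without overlap between the groups. Hoxc8 had 751 counts over the 3 HD libraries and 0 over the 3 WT libraries, at least 228-fold higher at a floor of 3 counts over the group (edgeR adjusted p = 0.0141). Hoxc5 had 1001 against 1 count, a ratio of 911 with a counting interval of 163 to 36010, and Hoxc6 had 497 against 1 count, a ratio of 452 with an interval of 80.8 to 17900 (edgeR adjusted p = 0.000549 and 0.0014). Hoxc4 rose by 8.09 ± 0.76 on the log2 scale to 7.43 ± 4.32 CPM. Pax2 and Wt1, regulators of kidney and hindbrain development, rose by 5.05 ± 0.59 and 4.04 ± 0.59 (edgeR adjusted p = 7e-04 and 0.00377). C130021I20Rik, an antisense transcript, rose by 6.30 ± 0.33 (edgeR adjusted p = 1.87e-06). In GENCODE M21 (GRCm38) Hoxc8 lies on chromosome 15 at 102990607 to 102994111 inside the annotated span of Hoxc5 (102967443 to 103017429), which also covers Hoxc6. How reads were shared among these genes thus depends on the authors' counting, and whether reads were counted by strand is not stated. C130021I20Rik lies on the plus strand of chromosome 2 at 33641193 to 33646354. It does not overlap the adjacent Lmx1b (33560965 to 33640511, minus strand), which is named below.

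Genes with the largest falls outside those lists were Gpx6, a glutathione peroxidase, which fell by 4.98 ± 0.51 on the log2 scale (edgeR adjusted p = 0.000299), and Slc4a11, a membrane ion transporter, which fell by 2.94 ± 0.19 (edgeR adjusted p = 4.96e-06). Mas1, a receptor of the angiotensin system, changed by -3.28 ± 0.66, Abi3bp, an extracellular matrix protein, by -2.71 ± 0.56, and Ptpn7, a tyrosine phosphatase, by -2.68 ± 0.41 (edgeR adjusted p = 0.022, 0.0284 and 0.00382). Abi3bp varied widely among the cGAS-KO libraries, at 36.1 ± 30.1 CPM.

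Circadian clock genes fell in HD. Of 19 measured members, 8 fell, none rose and 11 were not called (12 fell and 1 rose adjusted over the list alone), with a median log2 change of -0.43. Dbp, an output transcription factor of the clock, fell from 133 ± 4.13 to 66.5 ± 4.51 CPM (edgeR adjusted p = 8.45e-06), and the repressor Ciart fell from 25.3 ± 3.05 to 11.0 ± 0.461 CPM (-1.21 ± 0.10, edgeR adjusted p = 5.06e-05). Per3 changed by -0.65 ± 0.09 and Bhlhe41 by -0.37 ± 0.07. The list test gave a camera adjusted p of 1.53e-10 and an adjusted p of 0.0405 with an estimated correlation.

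Other neuronal lists held fewer called genes. Glutamatergic and scaffold synapse genes had 6 of 36 members lower, 1 higher and 29 not called (13 lower and 1 higher adjusted over the list alone), among them Camk2b, a kinase subunit of the synapse (-0.63 ± 0.10), the scaffolds Dlg4 (-0.52 ± 0.10) and Dlgap3 (-0.58 ± 0.12), and the receptor Grm3 (-0.55 ± 0.12). The camera adjusted p was 7.67e-09, and the adjusted p was 0.562 with an estimated correlation. Striatal interneuron genes had 3 of 20 members lower (5 adjusted over the list alone): Nos1, which makes nitric oxide, at -0.56 ± 0.09, the transcription factor Lhx6 at -0.50 ± 0.12 and the hormone-related peptide Pthlh at -0.96 ± 0.25 (camera adjusted p = 0.00113, adjusted p = 0.443 with an estimated correlation). Cortical projection neuron genes had 3 of 29 members lower and Pcdh20, a protocadherin, higher (10 lower and 1 higher adjusted over the list alone). The lower members were Rspo1, Itpka and Ngef, at -0.71 ± 0.14, -1.27 ± 0.25 and -0.95 ± 0.21, and medium spiny neurons also express Itpka and Ngef (list median -1.02, camera adjusted p = 2.83e-07, adjusted p = 0.63 with an estimated correlation). Of 23 immediate early genes, the fast responders to neuronal activity, 1 fell, the clock gene Per1, at -0.74 ± 0.17 (camera adjusted p = 0.000138, adjusted p = 0.724 with an estimated correlation). In the cortical, synapse and immediate early lists WT replicate 1 lay nearer to HD than WT replicates 2 and 3 did. The mean log2 CPM of the cortical list was 5.27 and 5.44 in WT replicates 2 and 3 but 3.87 in WT replicate 1, inside the HD range of 3.64 to 4.03. The synapse list was at 8.30 and 8.35 in WT replicates 2 and 3 and 7.99 in WT replicate 1, against 7.84 to 7.92 in HD, and the immediate early list at 4.63, 5.06 and 3.66, against 3.57 to 4.11 in HD.

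Of 51 tested interferon response genes, 5 rose in HD, none fell and 46 were not called (6 and 0 adjusted over the list alone), with a median log2 change of 0.36. Eif2ak2, the kinase that senses double-stranded RNA, rose by 0.71 ± 0.14, Ifit2 by 0.60 ± 0.12, Parp12 by 0.42 ± 0.09 and Mx2, a polymorphic pseudogene in GENCODE M21, by 0.85 ± 0.21 (edgeR adjusted p = 0.0132, 0.0157, 0.0173 and 0.0423). The list's camera adjusted p was 3.57e-06, its fry adjusted p 0.178 and its adjusted p 0.63 with an estimated correlation. Of 36 cGAS-STING pathway components, 2 rose and none fell, both over all genes and adjusted over the list alone: the ubiquitin ligase Trim56 (0.69 ± 0.14) and Enpp1, which degrades the cGAS product cGAMP (0.53 ± 0.12), with a camera adjusted p of 0.0461, a fry adjusted p of 0.0912 and an adjusted p of 0.559 with an estimated correlation. Of 22 antigen presentation genes, 1 rose (2 adjusted over the list alone), Psme1, a proteasome activator, at 0.32 ± 0.07 (camera adjusted p = 0.00875, adjusted p = 0.712 with an estimated correlation). WT replicate 1 lay inside the HD range in the interferon, cGAS-STING and antigen presentation lists. Its mean log2 CPM was 1.85, 3.24 and 3.42, against HD ranges of 1.85 to 2.15, 3.12 to 3.26 and 3.19 to 3.45. WT replicates 2 and 3 were at 1.55 and 1.48, 3.01 and 2.97, and 3.07 and 2.92. No member of the microglia, disease-associated microglia, complement or inflammatory cytokine lists was called, over all genes or adjusted over the list alone, and camera gave adjusted p = 0.478, 0.789, 0.0795 and 0.478 for them. Without WT replicate 1 the disease-associated microglia list went upward (camera adjusted p = 0.0309), and the complement list went downward at 0.0044, 0.00364 and 0.0222 without WT replicate 2, WT replicate 3 and HD replicate 2. Inpp5d, Lpl, C4a and Ptgs2 had the smallest p in these lists, at -0.28 ± 0.09, -0.68 ± 0.18, -0.71 ± 0.21 and -1.46 ± 0.60 (edgeR adjusted p = 0.106, 0.0523, 0.0813 and 0.219).

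Glial lists held genes that went both ways. Enpp6, which marks newly formed oligodendrocytes, rose from 16.6 ± 0.97 to 39.0 ± 3.43 CPM (log2 change 1.24 ± 0.10, edgeR adjusted p = 2.7e-05), while Cldn11 and Fa2h, which serve mature myelin, changed by -0.49 ± 0.10 and -0.37 ± 0.09. In that list of 30 genes 1 rose, 2 fell and 27 were not called (6 and 5 adjusted over the list alone, camera adjusted p = 0.048 upward, adjusted p = 0.895 with an estimated correlation). The list's mean log2 CPM in WT replicate 1 was 7.20, above the HD range of 7.05 to 7.18. WT replicates 2 and 3 were both at 6.91. Astrocyte genes had 3 of 22 members lower, Glul, which makes glutamine, at -0.56 ± 0.10, the glutamate transporter Slc1a2 at -0.65 ± 0.12 and F3 at -0.34 ± 0.08, with S100b higher at 0.61 ± 0.13 (2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.388). Cp, the copper protein ceruloplasmin, rose by 0.66 ± 0.12 and was the member called among 25 reactive astrocyte genes (camera adjusted p = 0.841 downward, and 0.0234 upward without WT replicate 1). Cacng4, an AMPA receptor subunit, fell by 0.44 ± 0.10 and was the member called among 14 oligodendrocyte precursor genes (camera adjusted p = 0.122).

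Lipid genes were called one by one, without a common direction. Cyp46a1, which clears cholesterol from neurons, fell by 0.61 ± 0.08 (edgeR adjusted p = 0.00114) and the lipoprotein receptor Scarb1 by 0.42 ± 0.09, while the cholesterol transporters Npc1 and Abca1 rose by 0.32 ± 0.07 and 0.41 ± 0.10. That transport list had 3 members up, 2 down and 16 not called (the same counts adjusted over the list alone, camera adjusted p = 0.751). Pla2g4a, the phospholipase that releases arachidonic acid, rose by 1.08 ± 0.14, and Dgat2, Lpcat4 and Mgll, which make or split glycerolipids, changed by -0.65 ± 0.13, -0.58 ± 0.14 and -0.54 ± 0.14 (1 up and 3 down of 55, 3 and 6 adjusted over the list alone, camera adjusted p = 0.233). Smpd3, a sphingomyelinase, and Fa2h fell and Sptlc2, of the first step of sphingolipid synthesis, rose, at -0.82 ± 0.15, -0.37 ± 0.09 and 0.38 ± 0.09 (1 up and 2 down of 40, 1 and 3 adjusted over the list alone, camera adjusted p = 0.94). No gene of cholesterol synthesis, fatty acid synthesis or fatty acid oxidation was called over all genes (camera adjusted p = 0.0832, 0.73 and 0.00164). The last list passed camera upward with 4 of 29 members higher adjusted over the list alone, and its adjusted p was 0.654 with an estimated correlation. Its mean log2 CPM in WT replicate 1 was 4.64, inside the HD range of 4.57 to 4.66. WT replicates 2 and 3 were at 4.32 and 4.34. In the fatty acid lists Fads1 and Acadm came closest, at -0.26 ± 0.07 and 0.26 ± 0.08.

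Among the other lists, camera called nuclear oxidative phosphorylation genes up (adjusted p = 0.00725), mitochondrially encoded transcripts down (0.048), erythrocyte genes down (0.00166) and genes of thalamus, septum and pallidum up (0.048). Their adjusted p with an estimated correlation were 0.63, 0.86, 0.475 and 0.823. Hba-a2, an alpha-globin gene that shares near-identical sequence with Hba-a1, was the member called over all genes, at -1.21 ± 0.30, and 5 of 7 erythrocyte genes were lower adjusted over the list alone. Eda2r, a receptor induced by p53, rose by 1.02 ± 0.22 and the chaperone Hsp90aa1 by 0.34 ± 0.08, the called members of 30 p53 and senescence genes and of 28 heat shock and unfolded protein genes (camera adjusted p = 0.841 and 0.789). Camera called none of the endothelial, fibroblast, choroid plexus, autophagy, sex-linked and C57BL/6 substrain lists (adjusted p = 0.0568, 0.789, 0.131, 0.624, 0.789 and 0.789), and none of their members was called. In all, 873 of 21309 genes passed, 304 higher and 569 lower, of which 292 changed by more than 2-fold. The count moved with single libraries: it was 1532 without WT replicate 1, 282 and 247 without WT replicates 2 and 3, and 265 and 324 without HD replicates 2 and 3. Without WT replicate 1 and cGAS-KO replicate 3, the libraries farthest from their groups, it was 3589, a setting in which every library without the knock-in allele is low in Xist.

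**Figure D2:**
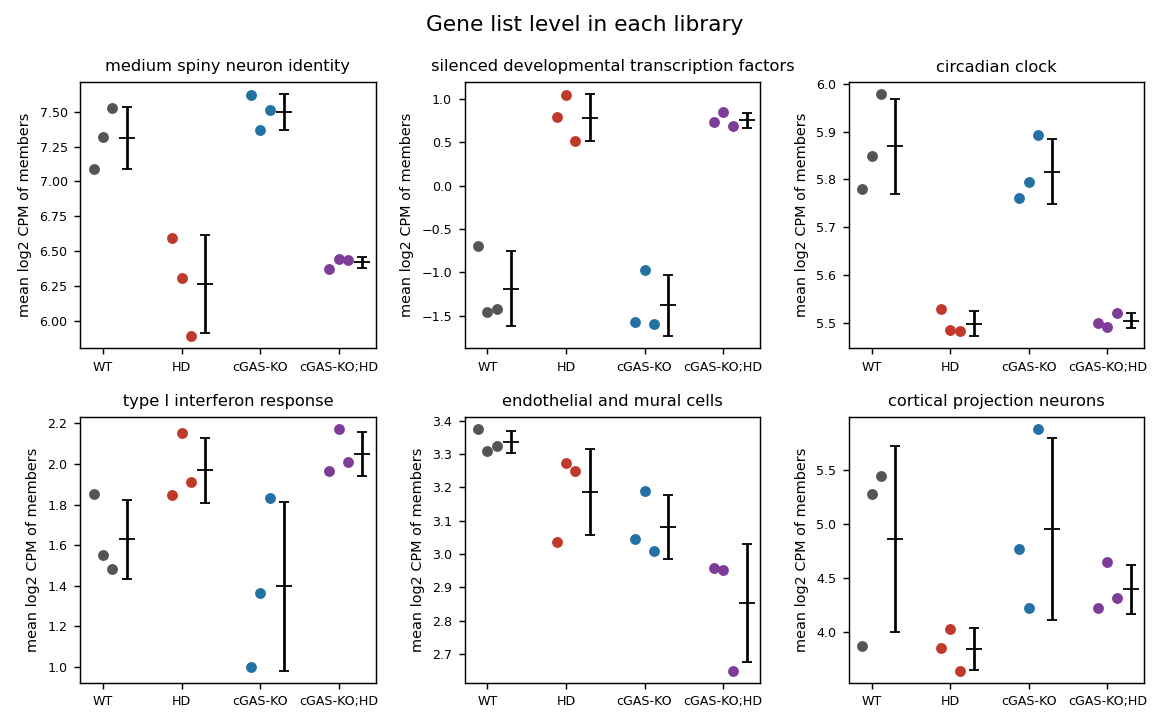
Mean log2 CPM of the members of 6 gene lists in each library, by group, with dots for libraries and a bar with whiskers for the mean ± SD of 3 libraries. Medium spiny neuron genes lie lower, and silenced developmental genes higher, in the HD and double-mutant libraries than in the WT and cGAS-KO libraries.

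The double mutants against cGAS-KO ask what the knock-in allele does when cGAS is absent. Medium spiny neuron genes fell here too. Of 45 members, 34 fell and none rose (44 and 0 adjusted over the list alone), with a median of -1.09 (camera adjusted p = 2.95e-86, adjusted p = 0.0465 with an estimated correlation). Scn4b fell by 2.66 ± 0.20 on the log2 scale, from 568 ± 120 to 89.8 ± 22.2 CPM, and Ryr1 by 2.21 ± 0.13, from 44.1 ± 3.44 to 9.55 ± 0.703 CPM (edgeR adjusted p = 4.64e-05 and 3e-06). Adora2a changed by -2.04 ± 0.20 and Rasgrp2 by -1.22 ± 0.11. Of the silenced developmental genes, 6 of the 21 tested rose (11 adjusted over the list alone, camera adjusted p = 3.52e-16, 2.01e-12 without the low-count filter, adjusted p = 0.0222 with an estimated correlation). Hoxc8 had 1187 counts over the double mutants and 0 over cGAS-KO, at least 341-fold higher, and Hoxc6 had 748 against 0, at least 215-fold higher. Hoxc4 had 2080 against 2 counts, a ratio of 896 (counting interval 248 to 7405), and Hoxc5 had 1375 against 3, a ratio of 395 (135 to 1918). Pax2 rose by 4.61 ± 0.53 and Wt1 by 4.82 ± 0.62. Lmx1b, a homeobox factor of midbrain dopamine neurons, rose by 6.33 ± 0.46 to 6.69 ± 0.207 CPM (edgeR adjusted p = 1.69e-05). The largest falls were in Gpx6 (-4.78 ± 0.52), Arhgef39 (-3.37 ± 0.26), Gm9754 (-2.84 ± 0.37), the transcription factor Mafa (-2.82 ± 0.23) and Slc4a11 (-2.73 ± 0.19).

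Of 51 interferon response genes, 9 rose without cGAS, none fell and 42 were not called (21 and 0 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 1.66e-15, fry adjusted p = 0.0341, adjusted p = 0.301 with an estimated correlation). Parp12 rose by 0.61 ± 0.09, the ubiquitin ligase Trim25 by 0.73 ± 0.12, Eif2ak2 by 0.79 ± 0.14 and Epsti1 by 0.87 ± 0.18 (edgeR adjusted p = 0.00185, 0.00587, 0.00687 and 0.0156). Of the cGAS-STING components, Trim56 and Enpp1 rose, at 0.80 ± 0.14 and 0.56 ± 0.12 (2 of 36, 4 adjusted over the list alone, camera adjusted p = 7.72e-05, fry adjusted p = 0.00521, adjusted p = 0.0957 with an estimated correlation). Antigen presentation genes Psme1 and Tapbpl rose by 0.34 ± 0.07 and 0.47 ± 0.11 (2 of 22, 3 adjusted over the list alone, camera adjusted p = 4.93e-05, adjusted p = 0.498 with an estimated correlation). Ctss, a lysosomal protease of microglia, rose by 0.55 ± 0.13, the member called of 28 microglial genes (camera adjusted p = 0.000326, adjusted p = 0.609 with an estimated correlation). Lpl, a lipase, fell by 0.74 ± 0.18 in the disease-associated microglia list, which went upward as a whole (camera adjusted p = 0.0155, adjusted p = 0.646 with an estimated correlation). The reactive astrocyte genes Cp and Vim rose by 0.90 ± 0.12 and 0.86 ± 0.19 (2 of 25, camera adjusted p = 0.000612, adjusted p = 0.621 with an estimated correlation). Library cGAS-KO replicate 3, which stood apart in mitochondrial share, is among the 3 controls of each of these gene groups. Its mean log2 CPM for interferon genes was 1.83, against 1.00 and 1.36 in cGAS-KO replicates 1 and 2 and 1.97 to 2.17 in the double mutants. It was also the control nearest to the double mutants in the cGAS-STING, antigen presentation and both microglia lists. For reactive astrocytes it was farthest, at 1.81 against 1.88 and 1.99 (double mutants 2.18 to 2.37).

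Clock genes fell, with 7 of 19 lower and none higher (10 and 0 adjusted over the list alone, camera adjusted p = 6.51e-08, adjusted p = 0.0539 with an estimated correlation). Dbp fell by 0.65 ± 0.07 and Ciart by 0.76 ± 0.10, from cGAS-KO levels of 107 ± 5.91 and 16.0 ± 0.774 CPM, and Hlf and Npas2, transcription factors of the clock and its output, changed by -0.71 ± 0.14 and -1.05 ± 0.21. Synapse genes had 5 of 36 members lower (14 adjusted over the list alone), with Camk2b, Shank3, Dlgap3 and Dlg4 at -0.62 ± 0.10, -0.61 ± 0.10, -0.60 ± 0.12 and -0.44 ± 0.10 (camera adjusted p = 2.24e-10, adjusted p = 0.498 with an estimated correlation). Among oligodendrocyte genes 6 rose and 1 fell of 30 (10 and 7 adjusted over the list alone), with Enpp6 at 1.13 ± 0.10, Sox10 at 0.42 ± 0.07, Gjb1 at 0.49 ± 0.11 and Apod at 0.65 ± 0.16 (camera adjusted p = 0.00442, adjusted p = 0.685 with an estimated correlation). Cacng4 fell by 0.52 ± 0.10 and Gpr17, of differentiating precursors, rose by 0.46 ± 0.10. S100b rose by 0.77 ± 0.13 and Slc1a2 and Glul changed by -0.57 ± 0.12 and -0.41 ± 0.10. Cyp46a1 fell by 0.70 ± 0.08, Fads1, a fatty acid desaturase, by 0.32 ± 0.07, Smpd3 by 0.76 ± 0.15 and Dgat2 by 0.60 ± 0.13, while Npc1, Pla2g4a, Plin3 and Lpcat2 rose by 0.33 ± 0.07, 1.13 ± 0.14, 0.62 ± 0.13 and 0.36 ± 0.09. No cholesterol synthesis gene was called over all genes, and 11 of 26 were lower adjusted over the list alone (camera adjusted p = 4.28e-05 downward, adjusted p = 0.498 with an estimated correlation). Cdkn2a, a cell cycle inhibitor of senescent cells, rose by 2.32 ± 0.42 at under 1 CPM (edgeR adjusted p = 0.00855), Eda2r rose by 0.98 ± 0.22, and Zmat3, a p53 target, fell by 0.30 ± 0.07. Camera also called immediate early, cortical projection neuron and endothelial genes down (adjusted p = 1.68e-07, 0.000185 and 0.00758) and fibroblast and fatty acid oxidation genes up (0.00972 and 0.000642), at adjusted p = 0.573, 0.631, 0.609, 0.631 and 0.609 with an estimated correlation. The cortical list's mean log2 CPM was 4.77, 4.22 and 5.88 in cGAS-KO replicates 1, 2 and 3, against 4.22 to 4.65 in the double mutants. The oligodendrocyte list was at 6.93, 7.04 and 6.62, against 7.00 to 7.05. In both lists cGAS-KO replicate 2 lay at the double-mutant level and cGAS-KO replicate 3 farthest from it. Per1 (-0.75 ± 0.17), Rspo1 (-0.62 ± 0.14) and Itpka (-1.11 ± 0.25) fell, while Egfl7 (-0.48 ± 0.13), Col3a1 (1.16 ± 0.34) and Hadha (0.35 ± 0.09) were not called. In all, 843 genes passed, 307 higher and 536 lower. The count was 386 without cGAS-KO replicate 1 and 339, 321 and 475 without double-mutant replicates 1, 2 and 3, it was 460 when fitted on the compared groups alone, and it was 1805 without WT replicate 1 and cGAS-KO replicate 3.

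The knock-in effects with and without cGAS were set against each other in the same genes. Of the genes that rose, 160 were shared by the lists of 304 and 307, where independent lists would share 4.38, and of those that fell, 343 were shared by the lists of 569 and 536, against 14.3. No gene was called in opposite directions, and 98.6% of the 873 genes called in HD against WT had the same sign in the double mutants against cGAS-KO. These comparisons share no library. Across all 21309 genes, which are not independent replicates, the log2 changes correlated with r = 0.609, against a mean of -0.004 in 20 simulations without any effect and 0.634 (0.618 to 0.649) in 20 simulations with one knock-in effect in both backgrounds. The correlation depended on the genes kept, at 0.1325 without the low-count filter and 0.8158 with the stricter filter. Over the 873 genes the slope was 0.926, against 0.854 (0.821 to 0.897) in the simulations with one knock-in effect, and the covariance over all genes was 0.186, against 0.244 (0.236 to 0.252). Each simulated slope used the 873 genes with the smallest p in HD against WT. These simulations called 1394 genes there on average, so the slopes are not over like genes. The interaction, a direct test of whether the knock-in effect differs between the backgrounds, called 1 gene, Mid1-ps1. It called none of Htt, Cgas, Ryr1, Scn4b, Dbp or any of the Hoxc genes, and 606 genes had an unadjusted p under 0.05, where chance gives 1065. That number was 3253 of 21724 genes without WT replicate 1 and cGAS-KO replicate 3, and 439 of 21922 without double-mutant replicate 2. The median SE over genes was 0.243 for the interaction, against 0.172 in HD against WT. No interaction was planted in the simulated counts, so its power is not known. The lack of further calls thus does not show that the knock-in effects are equal. For the interaction DESeq2 called 3 genes and limma-voom called 0, the count was 0 without any one of WT replicate 2 or 3, HD replicate 1 or 3, cGAS-KO replicate 1 and double-mutant replicate 1 or 2, and it was 105 without WT replicate 1 and cGAS-KO replicate 3 together. In that last setting cortical projection neuron genes were at a mean log2 CPM of 5.27 and 5.44 in WT and 4.77 and 4.22 in cGAS-KO. The 105 calls were not separated from such a difference in tissue content.

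**Figure D3:**
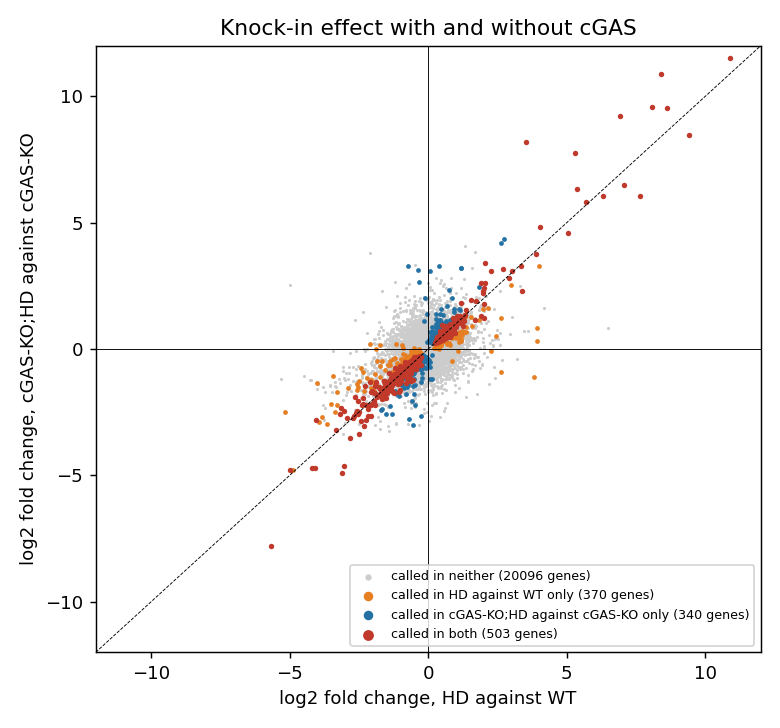
Log2 fold change of each of 21309 genes in the double mutants against cGAS-KO (vertical) plotted against that in HD against WT (horizontal), coloured by which comparison called the gene, with the line of equal change dashed. The 503 genes called in both lie along the dashed line, and none is called in opposite directions.

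The double mutants against HD ask what loss of cGAS does in knock-in mice. The gene that passed was Mid1-ps1, a pseudogene of the ubiquitin ligase gene Mid1, which fell by 2.85 ± 0.23 on the log2 scale, from 6.43 ± 0.813 to 0.89 ± 0.175 CPM (edgeR adjusted p = 0.000446, 1 of 21309 genes). It measured 0.418 ± 0.0636 CPM in WT and 0.493 ± 0.138 CPM in cGAS-KO, and its interaction was -3.08 ± 0.35 (edgeR adjusted p = 0.0168). GENCODE M21 places it on the Y chromosome of GRCm38 at 90753057 to 90763485, yet HD replicates 1 and 2, with 2 and 1 counts of Ddx3y, had 6.96 and 5.50 CPM of it, so its reads cannot be told from those of copies elsewhere. DESeq2 called 7 genes in this comparison, limma-voom 1, and 1232 genes had an unadjusted p under 0.05, where chance gives 1065. That number moved with the fit, at 2752 of 20286 genes when these groups alone were fitted and 526 of 21856 without HD replicate 3. Without WT replicate 1 and cGAS-KO replicate 3, which are not in this comparison, it was 3410 of 21724. Each of these fits called 1 gene. The number thus depended on the libraries that set the shared spread.

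In the double mutants against HD no member of the 36 gene lists was called over all genes. Medium spiny neuron genes had a median log2 change of 0.14 with no member called, over all genes or adjusted over the list alone (camera adjusted p = 0.00148 upward, adjusted p = 0.856 with an estimated correlation). Scn4b, with the smallest p in that list, was at -0.51 ± 0.19, against the list's direction, and camera turned to a downward direction at adjusted p = 0.617 without HD replicate 3. Endothelial and mural genes had a median of -0.35, with none of 26 called over all genes and 6 lower adjusted over the list alone, led by Cldn5, a tight junction protein, at -1.07 ± 0.23 (camera adjusted p = 9.87e-10, adjusted p = 0.622 with an estimated correlation). Interneuron genes had 2 of 20 higher adjusted over the list alone, led by Lhx6 at 0.56 ± 0.12 (camera adjusted p = 0.000838, adjusted p = 0.704 with an estimated correlation). Camera also called microglia, cortical projection neuron and mitochondrially encoded genes up, at medians of 0.18, 0.46 and 0.26 (adjusted p = 0.000362, 0.00148 and 0.0445), and oligodendrocyte, glycerophospholipid and nuclear oxidative phosphorylation genes down (0.0369, 0.0428 and 3.99e-05). Selplg (0.44 ± 0.13), Cux2 (-0.29 ± 0.13), mt-Nd5 (0.46 ± 0.31), Mog (-0.29 ± 0.13), Cds1 (-0.38 ± 0.09) and Ndufs4 (-0.31 ± 0.08) had the smallest p in these lists, and none of the 36 lists passed with an estimated correlation, where the lowest adjusted p was 0.622, or with fry, where it was 0.386. Interferon response and cGAS-STING lists were not called, at medians of 0.05 and 0.03 (camera adjusted p = 0.495 and 0.515), nor were cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and sphingolipid genes (0.097, 0.177, 0.275 and 0.752).

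Whether loss of cGAS moved genes back from their HD level was counted in the genes called in HD against WT. Of these 873, 71.9% changed in the opposite direction in the double mutants against HD. Both comparisons use the 3 HD libraries, so the share is above 50% without any effect of cGAS: it was 89.7% in simulated groups without any effect and 66.4% (62.4% to 69.3%) in simulated groups with the knock-in effect alone. In the genes called without cGAS the share, taken against the knock-in effect without cGAS, was 45.9%, against 32.3% (28.8% to 35%) simulated. There both comparisons use the double-mutant libraries, so the share is not on the scale of the 71.9%. Among the 45 medium spiny neuron genes it was 84.4%, against 51% (35.6% to 60%) simulated, while the median of the list was 0.14 against a knock-in median of -1.06. The covariance of both effects over all genes was -0.0929, against -0.0694 (-0.0806 to -0.0601) simulated. The simulated shares of called genes were taken over the same number of genes with the smallest p. In HD against WT the simulations called 0.4 genes on average without any effect and 1394 with the knock-in alone. Real and simulated genes were thus not chosen alike, so the distance between their shares in called genes does not measure an effect of cGAS. The simulated genes varied independently of each other, so these ranges are narrower than real genes would give, and the HD libraries are too few to split.

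The cGAS-KO group against WT asks what loss of cGAS does without the knock-in allele. No gene passed. The lowest edgeR adjusted p was 0.449, for Ciart, which measured 16.0 ± 0.774 against 25.3 ± 3.05 CPM (log2 change -0.66 ± 0.10), and 913 genes had an unadjusted p under 0.05, where chance gives 1065. DESeq2 called 6 genes and limma-voom 0. Fitted on these groups alone, 436 of 20020 genes had an unadjusted p under 0.05. Without WT replicate 1 and cGAS-KO replicate 3 that number was 1769 of 21724, and edgeR called 38 genes, all lower in cGAS-KO. In that setting camera called the cortical projection neuron list lower in cGAS-KO (adjusted p = 1.76e-18). The list's mean log2 CPM was 5.27 and 5.44 in the WT libraries left and 4.77 and 4.22 in the cGAS-KO libraries left. The 38 calls were thus not separated from a difference in tissue content. With all 12 libraries camera called 14 of the lists, and none passed with an estimated correlation (lowest adjusted p = 0.558) or with fry (0.413). Those with the smallest camera adjusted p were reactive astrocytes, at a median of -0.28 (1.61e-08), endothelial and mural cells, at -0.25 (1.61e-08), medium spiny neuron genes, at 0.19 (4.19e-08), and disease-associated microglia, at -0.38 (7.76e-08). WT replicate 1 stood apart in both glial lists: its mean log2 CPM was 2.90 for reactive astrocytes and 4.79 for disease-associated microglia, against 2.16 and 1.94, and 3.89 and 3.81, in WT replicates 2 and 3. Without it camera called 7 lists in place of 14, reactive astrocytes at 0.022, and disease-associated microglia (0.0764) and medium spiny neuron genes were no longer called. Lcn2 (log2 change -5.09), Slc2a1, the glucose transporter of vessels (-0.35 ± 0.10), Rgs4 (0.41 ± 0.14) and Lgals3 (-1.09 ± 0.35) had the smallest p in them, and Lcn2 varied widely among WT libraries, at 0.802 ± 1.19 CPM. Lists of complement, interferon, antigen presentation, oligodendrocyte, fibroblast, microglia, inflammatory and glycerophospholipid genes were called down and synapse and immediate early genes up by camera, with 0 or 1 member each lower adjusted over the list alone, against 3 of 26 endothelial genes. Psmb9 of the immunoproteasome (-1.05 ± 0.26) and the complement gene C4a (-0.83 ± 0.21) had the smallest p in theirs. The direction of several lists turned without WT replicate 1 or cGAS-KO replicate 3: the cortical projection neuron list, upward in all 12 libraries (camera adjusted p = 0.261), went downward at 0.022 and 0.0015, and the choroid plexus list, downward in all 12 (0.395), went upward at 1.38e-07 without WT replicate 1.

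With the cGAS genotypes averaged, the knock-in allele changed 2816 genes, 1191 higher and 1625 lower. The 5 rises with the smallest p were in C130021I20Rik (6.18 ± 0.23), the channel-like gene Tmc3 (3.07 ± 0.13), Lmx1b (5.85 ± 0.31), Enpp6 (1.18 ± 0.07) and the guidance cue Sema3d (1.09 ± 0.07), and the 5 falls were in Ryr1 (-2.24 ± 0.09), Ptprv (-2.51 ± 0.12), Slc4a11 (-2.83 ± 0.14), Abhd11os (-2.26 ± 0.13) and Hrk, a regulator of cell death (-1.66 ± 0.10). Of the 45 medium spiny neuron genes 44 fell, and of the 21 silenced developmental genes tested 10 rose (44 and 12 adjusted over the list alone, adjusted p = 0.0254 and 0.0211 with an estimated correlation). In the interferon list 18 of 51 rose and none fell (29 adjusted over the list alone, adjusted p = 0.471 with an estimated correlation, fry adjusted p = 0.0168), with Irf7, the interferon-induced master regulator, at 1.05 ± 0.22 and Trim21 at 0.63 ± 0.14 among the cGAS-STING components. Clock genes fell in 12 of 19 members and none rose (13 and 1 adjusted over the list alone, adjusted p = 0.0254 with an estimated correlation). Activity-regulated genes Egr2 (-2.02 ± 0.44), Egr3 (-0.94 ± 0.24) and Dusp1 (-0.69 ± 0.19) fell, 6 of 23 (14 adjusted over the list alone, adjusted p = 0.5 with an estimated correlation). Interneuron peptides Sst and Cort changed by -0.62 ± 0.17 and -1.90 ± 0.55. Of 26 cholesterol synthesis genes 9 fell (12 adjusted over the list alone), among them Msmo1 (-0.38 ± 0.09), Fdft1 (-0.24 ± 0.06), Idi1 (-0.25 ± 0.07) and the regulator Srebf2 (-0.22 ± 0.06), with camera adjusted p = 0.00167, fry adjusted p = 0.0285 and adjusted p = 0.5 with an estimated correlation. Of 29 fatty acid oxidation genes 8 rose (11 adjusted over the list alone), Hadha by 0.32 ± 0.07 and Eci2, Hsd17b4 and Decr1 by 0.24 ± 0.05, 0.27 ± 0.07 and 0.25 ± 0.06 (camera adjusted p = 0.000418, fry adjusted p = 0.0321, adjusted p = 0.5 with an estimated correlation). Endothelial genes Esam, Flt1 and Egfl7 fell by 0.63 ± 0.13, 0.40 ± 0.10 and 0.30 ± 0.09 (3 of 26, camera adjusted p = 0.014, adjusted p = 0.583 with an estimated correlation). The microglial genes Ctss, Sall1 and Tmem119 rose by 0.36 ± 0.09, 0.23 ± 0.07 and 0.27 ± 0.08 (3 of 28, camera adjusted p = 0.206). The count was 1784 and 1803 without WT replicates 2 and 3. It was 235 in the 6 high-Xist libraries alone, of which 227 were among the 2816, and 1350 in the 6 low-Xist libraries alone, of which 1171 were. The high-Xist libraries without the knock-in allele were WT replicate 1 and cGAS-KO replicate 3, the libraries farthest from their groups. These counts thus do not compare the knock-in effect between Xist classes.

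With the HD genotypes averaged, loss of cGAS changed no gene by edgeR (lowest adjusted p = 0.0991). DESeq2 called 10, limma-voom 0, and 1839 genes had an unadjusted p under 0.05, where chance gives 1065. Endothelial and mural genes had a median of -0.27 with 10 of 26 lower adjusted over the list alone, led by the growth factor receptor Flt1 at -0.48 ± 0.10 (camera adjusted p = 7.05e-14, fry adjusted p = 0.0851, adjusted p = 0.258 with an estimated correlation). Their mean log2 level differed by -0.29 between the 6 libraries without cGAS and the 6 with it (two-sided exact permutation over 924 splits, p = 0.00649, adjusted over the 36 lists 0.234). Camera called 12 of the 36 lists, among them medium spiny neuron genes up at a median of 0.17 (9.16e-08) and oligodendrocyte genes down at -0.12 (0.000262), and none passed with an estimated correlation (0.822 for both). The number of lists called was 5 without WT replicate 1 and 20 without WT replicate 3. Emp1 of the reactive astrocyte list (-0.55 ± 0.14), Lgals3 (-0.69 ± 0.24), Nos1 (0.24 ± 0.06) and Gsn (-0.27 ± 0.09) were not called.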

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

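The interaction test was fixed before the data were examined, and the tests of Mid1-ps1 below were chosen after its result was seen. Mid1-ps1 was singled out because the knock-in effect on it differed between mice with and without cGAS (interaction -3.08 ± 0.35, edgeR adjusted p = 0.0168). It was high in the HD group alone, at 6.43 CPM against 0.418 in WT, 0.493 in cGAS-KO and 0.89 in the double mutants. All 3 HD libraries lay above the other 9, whose highest value was 1.08 CPM, so the high HD mean did not rest on a single library. The call that singled the gene out made this likely beforehand, so it is not a separate test. Mid1, the parent gene, averaged 10 CPM in WT, 8.13 in cGAS-KO, 6.98 in HD and 5.08 in the double mutants, while the pseudogene gained 5.83 CPM over all other groups. HD thus lay below both groups without the knock-in, by less than that gain, and above the double mutants. The rule set for that test excluded reads moved from Mid1 as the source of the whole gain, and a part of it was left open. A structural or strain difference carried by the HD mice could not be tested with gene counts, so a biological explanation was not separated from it.

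Gene lists were singled out by the same interaction, each at camera's preset correlation. Those with a higher knock-in effect without cGAS were microglia (median difference 0.35, camera adjusted p = 4.16e-09), reactive astrocytes (0.35, 1.7e-06), complement (0.42, 4.24e-06), interferon response (0.21, 8.34e-05), fibroblasts and meninges (0.58, 8.34e-05), disease-associated microglia (0.21, 0.00024), erythrocytes (0.46, 0.00119), inflammatory cytokines (0.30, 0.00124), interneurons (0.08, 0.00944) and cGAS-STING components (0.10, 0.0411). Those with a lower effect were nuclear oxidative phosphorylation (-0.15, camera adjusted p = 4.49e-07) and cholesterol synthesis (-0.11, 0.00462). WT replicate 1 stood apart in several of these lists, with a mean log2 CPM of 4.90 for microglia, 2.90 for reactive astrocytes, 3.79 for complement, 4.79 for disease-associated microglia and 1.29 for inflammatory cytokines, against 4.56 and 4.53, 2.16 and 1.94, 3.20 and 3.21, 3.89 and 3.81, and 0.732 and 0.693 in WT replicates 2 and 3. Without it, disease-associated microglia (camera adjusted p = 0.39), interferon response (0.0845), inflammatory cytokines (0.197), cGAS-STING components (0.39) and cholesterol synthesis (0.159) were no longer called for the interaction, and the other 7 were. No member of any of these lists was called for the interaction. With an estimated correlation the adjusted p of these lists lay between 0.582 and 0.681, and with fry between 0.785 and 0.796. Inpp5d of the microglia list (0.40 ± 0.12), C4a of complement (0.81 ± 0.30) and Ndufs4 of oxidative phosphorylation (-0.41 ± 0.12) had the smallest p in their lists.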

How the results depend on the processing

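The settings without both libraries farthest from their groups (WT replicate 1 and cGAS-KO replicate 3), with Xist as a covariate and within one Xist class were chosen after the data were seen, and the others before. Medium spiny neuron genes stayed lower in the knock-in groups at every setting. Leaving out each library in turn gave camera adjusted p of 5.65e-103 to 1.42e-70 in HD against WT and 1.62e-78 to 1.79e-73 in the double mutants against cGAS-KO. These values hold at the preset correlation only. The correlation estimated for the list was 0.68 in both comparisons, where the adjusted p with all libraries was 0.0463 and 0.0465. Leaving out libraries was not repeated with an estimated correlation or with fry. The small p-values thus show a kept direction, and their size does not measure robustness. In each setting with both kinds of comparison, more genes were called for the knock-in than for cGAS, but the counts did not keep their size, and many calls of single genes named in the text were lost when a library was left out. Where values moved, the cause was not tested, apart from fewer libraries or genes in the fit.

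Counts of genes by DESeq2 were 1801 in HD against WT, 1662 in the double mutants against cGAS-KO, 7 in the double mutants against HD, 6 in cGAS-KO against WT, 3 for the interaction and 10 for cGAS averaged. With limma-voom the interaction had 0. At an adjusted p under 0.10 the counts were 1543, 1469 and, for cGAS averaged, 1. With a 1.5-fold threshold they were 536, 530 and, for the knock-in averaged, 1095. Without a low-count filter cGAS averaged had 2. Fitted on the compared groups alone, the double mutants against cGAS-KO had 460. The titles number the mice of each group, but same-numbered libraries were no closer than others (mean r = -0.0268 over 18 pairs, range -0.231 to 0.203, and 2 of 12 libraries closest to their own number), so they were not paired. With that number as a replicate block HD against WT had 507 and the double mutants against cGAS-KO had 596.

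Each library of the groups that a comparison uses was left out in turn. This gave 247 to 1532 genes in HD against WT, 321 to 1089 in the double mutants against cGAS-KO, 1 to 1 in the double mutants against HD, 0 to 0 in cGAS-KO against WT, 0 to 1 for the interaction, 1784 to 3596 for the knock-in averaged and 0 to 0 for cGAS averaged. Libraries of the other groups, which share in the estimate of spread, were not left out singly for the pairs of groups. Gene lists called ranged over 14 to 19, 16 to 20, 6 to 13, 7 to 23, 10 to 15, 13 to 20 and 5 to 20 in the same order. Of the 62 genes named for HD against WT, 38 were no longer called without WT replicate 3, 37 without HD replicate 2, 34 without WT replicate 2, 34 without HD replicate 3, 15 without HD replicate 1 and 4 without WT replicate 1, and 22 with the 1.5-fold threshold and 19 with the replicate block. Of the 62 named for the double mutants against cGAS-KO, 10 to 30 were lost without single libraries, most without double-mutant replicate 2. Of the 112 named for the knock-in averaged, 5 to 25 were lost without single libraries, 86 in the high-Xist libraries alone and 47 in the low-Xist libraries alone. WT replicate 1 gave the lowest and WT replicate 3 the highest number of lists in cGAS-KO against WT and for cGAS averaged.

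Without both distant libraries the counts were 3589 in HD against WT, 1805 in the double mutants against cGAS-KO, 38 in cGAS-KO against WT, 105 for the interaction and 4595 for the knock-in averaged. With Xist as a covariate in that setting they were 3412, 1731, 42 and 153, and 4 in the double mutants against HD. That setting leaves no high-Xist library without the knock-in allele. In it cortical projection neuron genes were higher in WT (mean log2 CPM 5.27 and 5.44) than in cGAS-KO (4.77 and 4.22). Tissue content was thus not separated from the calls in cGAS-KO against WT and for the interaction. The knock-in averaged had 235 genes in high-Xist libraries alone and 1350 in low-Xist libraries alone. In the high-Xist class the libraries without the knock-in allele were both distant libraries, so these counts do not compare the classes.

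With an estimated correlation camera called 3 lists in HD against WT, 2 in the double mutants against cGAS-KO, 0 in the double mutants against HD, 0 in cGAS-KO against WT, 0 for the interaction, 3 for the knock-in averaged and 0 for cGAS averaged. With fry HD against WT had 4, the double mutants against cGAS-KO had 5, the knock-in averaged had 12, and the double mutants against HD, cGAS-KO against WT, the interaction and cGAS averaged had 0.

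The correlation of both knock-in effects, 0.609 over all genes, was 0.1325 without a filter, 0.8158 with the strict filter, 0.9364 in genes called in HD against WT, 0.9471 in genes called in the double mutants against cGAS-KO, 0.4134 without both distant libraries and 0.4167 to 0.586 without each library in turn. The share of genes that changed opposite to the knock-in effect, 71.9%, was 84.44% in medium spiny neuron genes and 63.34% to 75.95% without each library in turn. In genes called without cGAS it was 45.91%, taken against the knock-in effect without cGAS. Simulations with the knock-in effect alone gave 66.4% for the 71.9% and 32.3% for the 45.91%, so these shares are not on 1 scale.

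Some lists turned in direction, given here with camera adjusted p. Without each library of the compared groups in turn these lay between 0.0309 and 0.985 for disease-associated microglia and 0.0234 and 0.967 for reactive astrocytes in HD against WT, and between 1.75e-13 and 0.617 for medium spiny neuron genes in the double mutants against HD. In cGAS-KO against WT they lay between 1.61e-05 and 0.847 for synapse genes, 6.85e-10 and 0.525 for immediate early genes, 1.38e-07 and 0.29 for choroid plexus, 0.0015 and 0.0649 for cortical neurons, 0.0114 and 0.956 for thalamic neurons and 1e-04 and 0.146 for mitochondrially encoded genes. For the interaction they lay between 8.01e-09 and 0.981 for medium spiny neuron genes and 0.00673 and 0.968 for synapse genes. The turns were these. In HD against WT without WT replicate 1, disease-associated microglia (0.0309) and reactive astrocytes (0.0234) went up, as they did without both distant libraries (0.0236 and 0.0184, and 0.0475 for reactive astrocytes with Xist as a covariate). In the double mutants against HD without HD replicate 3, medium spiny neuron genes went down (0.617). In cGAS-KO against WT without WT replicate 1, immediate early genes (0.46) and cortical neurons (0.022) went down and choroid plexus (1.38e-07) and thalamic neurons (0.022) up. There without cGAS-KO replicate 3, synapse genes (0.253), cortical neurons (0.0015) and mitochondrially encoded genes (1e-04) went down and thalamic neurons up (0.033). Without both distant libraries, and then with Xist as a covariate as well, cGAS-KO against WT had synapse genes (2.45e-09, 4.86e-10), immediate early genes (0.00475, 0.00115), cortical neurons (1.76e-18, 8.61e-23) and mitochondrially encoded genes (0.0144, 0.0236) down, and oligodendrocytes (0.0165, 0.0179), choroid plexus (3.82e-11, 4.86e-10), thalamic neurons (6.73e-06, 4.4e-07), fatty acid oxidation (0.00476, 0.00151) and glycerophospholipid genes (0.984, 0.959) up. The interaction in these settings had synapse genes (1.4e-09, 3.94e-10) and immediate early genes (0.0103, 8e-04) up, and oligodendrocytes (0.000142, 0.000149) and fatty acid oxidation (0.00398, 0.000993) down. It also had synapse genes up without cGAS-KO replicate 3 (0.00673) and medium spiny neuron genes up without HD replicate 1 (0.0164). For cGAS averaged, synapse genes (0.0732, 0.0557), immediate early genes (0.189, 0.357) and cortical neurons (0.0106, 0.00416) went down and choroid plexus (0.000733, 0.00132) up.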

Other observations

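Hox genes outside the named set rose with the knock-in averaged over cGAS genotypes. Hoxc9, Hoxc10 and Hoxd8 averaged 1.06, 0.604 and 0.455 CPM in the 6 knock-in libraries against 0, 0.00565 and 0.00265 CPM in the other 6 (edgeR adjusted p = 0.00019, 0.000335 and 0.00115). Hoxa7 and Hoxd1 were not called (log2 changes 1.57 ± 0.49 and 0.70 ± 0.57). A test of Hoxc genes against the other Hox clusters, chosen after the rise was seen, took only genes that passed the low-count filter and left out those that stayed silent, so it tells nothing about the clusters (two-sided Fisher's exact p = 0.133). Ttr, the transthyretin gene of the choroid plexus, ranged from 45.7 to 1896 CPM over the libraries.

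All tests in this paragraph were chosen after the fall in medium spiny neuron genes was seen, and the rule for Xist was written before that test was run. A smaller share of striatum in the knock-in dissections might lower these genes and raise those of the tissue in its place. The rules took every other tissue and cell list to rise alike. Which tissue would take that place is not known, and glial and vessel cells also lie in striatum. The rules thus cannot decide the question. The list scores of endothelial and mural cells differed by -0.189 ± 0.0698 between knock-in and other libraries and those of oligodendrocytes by 0.141 ± 0.0822, apart by -0.33 ± 0.0771 or 4.28 SE, above a Bonferroni bound of 4.12. By a first rule, written before that one, the highest list (thalamus, septum and pallidum neurons, 0.376 ± 0.255) and the lowest (cortical projection neurons, -0.789 ± 0.359) were apart by 1.94 SE, under its bound of 2. Astrocytes differed by -0.0209 ± 0.0788 and microglia by 0.074 ± 0.0803. The cortical, endothelial and astrocyte scores were not raised, the rules disagreed, and tissue share could not be excluded. In HD replicates 1, 2 and 3 the medium spiny neuron score was 6.59, 6.31 and 5.89. The thalamus, septum and pallidum score there was 5.34, 5.65 and 5.88. Both scores also ran inversely over the WT and over the double-mutant libraries, but not over cGAS-KO. Unequal numbers of high-Xist libraries were excluded, since the median change of the medium spiny neuron list was -1.13 with Xist as a covariate.

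The tests on clock genes were chosen after the fall in these genes was seen, with their rules written before they were run. A different time of day at collection could lower Dbp and its kin and raise genes of the opposite phase. Of 5 such genes none was called higher with the knock-in averaged over cGAS genotypes (0 of 5), Npas2 fell by 1.08 ± 0.15, and Arntl, Clock, Cry1 and Nfil3 were not called (0.08 ± 0.08, 0.02 ± 0.08, 0.16 ± 0.07 and 0.26 ± 0.09). Their median of 0.075 did not meet the rule for excluding a shift in time, which remains possible, and collection times are not given in the sources used here. With Xist as a covariate 12 clock genes were still lower, which excludes Xist level as the cause.

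Near the targeted genes, 13% of 207 genes within 10 Mb of Htt were called for the knock-in averaged against 13.2% elsewhere (two-sided Fisher's exact p = 1). Within 10 Mb of Cgas, 9.74% of 154 genes had an unadjusted p under 0.05 for cGAS averaged against 8.61% elsewhere (two-sided Fisher's exact p = 0.565).

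Libraries were also split in other ways into groups of the same sizes. For the knock-in averaged, 2816 genes were called in the real groups and at most 22 in the other splits, 1 of 100 as large with the real groups included. Chance alone is thus unlikely to give as many calls, but the splits do not test features that are unequal between the groups. Chance could not be excluded for the interaction, where the real groups gave 1 gene, 8 of 100 splits gave as many and the highest other split gave 145. For cGAS averaged the real groups gave 0, so all 100 splits gave at least as many by construction (highest 11) and the splits tell nothing. The pairs of groups allow 10 splits each, too few to exclude chance.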
